A study of Homo sapiens with 18 samples.

How the data were processed

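HTR8/SVneo cells, a trophoblast line derived from human placental explants and immortalised with a viral large T antigen, were profiled on Illumina expression arrays, which measure transcript levels through the brightness of gene-specific probes. Total RNA was amplified and labelled with biotin, and the RNA integrity number exceeded 9 in all samples, per the labels' protocols. The 18 arrays fell into 6 groups by substrate and oxygen. On uncoated plastic there were 3 arrays at 1% oxygen, 4 at 5% and 3 at 20%, and on Matrigel there were 3, 2 and 3. Groups and replicate numbers were taken from the sample titles. The labels' protocols speak of 3 replicates per oxygen concentration, so the groups of 4 and of 2 arrays depart from that plan. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

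The authors deposited 1 value per probe and array, on a log2 scale, for 47313 probes. The submitters' processing notes name lumi, limma and R 2.15.2 without saying what each was used for. The background correction and the transformation are not given in the sources used here, so the deposited log2 scale may be a variance-stabilised one that approaches log2 only at high signal. Values ran from 6.768 to 13.8, every array had a median near 7.05, and the sorted columns differed by at most 0.0066, which is what quantile normalization between arrays leaves behind. Whether the lower end of the scale is compressed was not settled, and if it is, differences of dim genes understate fold changes. Fold changes below are 2 to the power of the difference on the deposited scale. Arrays correlated with one another at 0.9909 to 0.9977 over all probes, and no pair shared more than 0.112% identical values, so no array was a copy of another. The number of arrays limits the precision, and detection p-values were not used here.

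Probes were named through GEO's platform annotation, with symbols updated through Entrez identifiers. A single gene was named for 30109 probes, several genes for 8 probes and none for 17196 probes. Of the single-gene probes, 30070 were matched by Entrez identifier and 39 kept the symbol of the annotation. Probes with several genes or none were left out of the main tests, and the unnamed probes were tested apart from the rest. A probe was kept when its mean over the 18 arrays exceeded the median of all probe means, 7.047, which left 23656 probes. Each gene was represented by its kept probe with the highest mean, giving 12886 genes, of which 3485 had more than 1 kept probe.

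One cell-means model with 6 group means was fitted to all 18 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that all groups shared 1 estimate of the spread. It had 12 residual and 6.68 prior degrees of freedom. There were 7 group comparisons, of which 6 compared oxygen levels within a substrate and 1 averaged the differences between Matrigel and plastic over the 3 oxygen levels with equal weights. A further 3 interaction contrasts subtracted the oxygen difference on plastic from that on Matrigel. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and all these tests were two-sided. Unless another fit is named, every adjusted p given for a gene comes from this limma fit, and ± after a difference is its standard error.

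Gene lists, 29 in number and together naming 605 genes of which 483 were tested, were written before the data were examined. Each was compared with all other genes by camera with a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Members that passed were counted with p-values adjusted over all genes tested and again adjusted over the list alone. The list counts are over all genes tested unless stated. Some genes are in several lists, so calls of different lists are not independent. The HIF targets share SLC2A1, PDK1, PFKFB3 and PFKFB4 with glycolysis, and VEGFA, ANGPTL4, ADM and EFNA3 with the angiogenic factors. They share KDM3A, KDM4B and KDM4C with the JmjC demethylases, and BNIP3 and BNIP3L with the apoptosis genes. The genes named below follow a rule that was also fixed before the data were examined. It takes the 8 largest increases and decreases per comparison among genes that passed and whose arrays did not overlap between the groups, up to 4 members of each described list by p, 14 oxygen-related or trophoblast genes, and the 5 interactions with the smallest p. For Matrigel versus plastic, non-overlap was replaced by 1 sign at all 3 oxygen levels. The text names fewer genes than the rule allows. CA9 and SERPINE1 had no named probe and were not analysed here.

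The scripts were first tested on simulated arrays drawn around the real gene means with the fitted spread, for 12886 genes. In a simulated 1% versus 5% oxygen comparison on plastic, 82% of 50 genes changed by 1.2-fold and 100% of those changed by 1.5-fold were recovered, beside 12 false calls. For 5% versus 20% oxygen on Matrigel the shares were 50% and 98%, and for the interaction of 1% versus 5% oxygen they were 28% and 96%. With no change simulated, these comparisons gave 0 calls. Alternatives covered the replicate number as a fixed or random block, other filters on dim probes, a second quantile normalization, centring of each array, the mean of a gene's probes or all probes separately, an intensity trend with a robust prior, array weights, only the arrays compared, leaving out each array in turn, a 1.5-fold minimum and a threshold of 0.01. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.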

Results

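Gene expression was measured in HTR8/SVneo cells, a trophoblast cell line, after 6 h in 1%, 5% or 20% oxygen. In each well 300000 cells were kept in 2 ml of medium with reduced serum, either on plastic or on a 15 µm layer of growth factor-reduced Matrigel, a basement membrane extract. The study took 1% oxygen as the condition in which hypoxia-inducible factor 1 (HIF-1) was expected to be active, 5% as physiological normoxia and 20% as standard culture. Matrigel stood for an endovascular-like state of the cells, and plastic for cells of the proximal cytotrophoblast column. The 1% and 5% cultures were held in a sealed chamber flushed with gas and the 20% cultures were not, so 20% oxygen differs from the others in handling too. There were 3, 4 and 3 arrays on plastic and 3, 2 and 3 on Matrigel, in rising order of oxygen. The first principal component held 49.5% of the variance and separated the substrates, and the second, with 11.6%, set the 1% arrays on plastic apart.

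The first comparison asked what 1% oxygen changed relative to 5% on plastic. Genes of the hypoxia response rose strongly. ANGPTL4, a secreted inhibitor of lipoprotein lipase, increased from 8.03 ± 0.028 (SD, n = 4) to 11.02 ± 0.12 (SD, n = 3), a 7.95-fold difference with an adjusted p of 6.4e-18; its dimmer probes, with means of 7.19 and 7.62, rose by 0.39 ± 0.032 and 0.84 ± 0.081 on the log2 scale. PFKFB4, a regulator of glycolytic flux, rose 5.11-fold, DDIT4, an inhibitor of mTOR signalling, 4.4-fold, BNIP3, a mitophagy receptor, 4.19-fold, NDRG1 4.08-fold and HK2, a hexokinase, 3.02-fold. The dimmer HK2 probe rose by 0.92 on the log2 scale, against 1.60. ANKRD37 and STC2, which encodes a secreted glycoprotein, rose 2.84-fold and 2.82-fold. In this comparison 526 of 12886 genes passed, 319 higher and 207 lower at 1% oxygen. Increases were larger than decreases: 43 genes rose and 5 fell by at least 1.5-fold, and of the 16 that changed at least 2-fold all rose.

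Of 37 measured HIF targets on plastic, 29 rose between 5% and 1% oxygen, none fell and 8 did not pass (32 rose adjusted over the list alone, camera adjusted p = 1.11e-81). Among them, SLC2A1, the main basal glucose transporter, rose by 1.11 ± 0.093 on the log2 scale and ADM, the precursor of the vasodilator peptide adrenomedullin, by 1.04 ± 0.074. VEGFA, a vascular growth factor, rose by 0.33 ± 0.048 and LOX, a collagen cross-linking enzyme, by 0.26 ± 0.043. The transcripts of the factors themselves did not pass: HIF1A differed by −0.006 ± 0.065 and EPAS1, which encodes HIF-2α, by 0.093 ± 0.058. PDK1 (0.14 ± 0.044, adjusted p = 0.0924, or 0.038 with an intensity trend and robust prior) and EGLN3 (0.066 ± 0.053) did not pass either. PDK1, EGLN3, LOX and VEGFA were dim, with mean levels over all arrays of 7.12, 7.19, 7.16 and 7.40. If the lower end of the scale is compressed, their differences understate fold changes. Small or missing changes of these genes, here and in the comparisons below, therefore do not show a weak or absent response. In the glycolysis list 14 of 22 members rose and none fell (18 adjusted over the list alone, adjusted p = 2.05e-31), including PFKFB3 by 0.86 ± 0.041 and SLC2A3 by 1.17 ± 0.065. Among 15 histone demethylases of the JmjC family, which use oxygen as a substrate, 3 rose (6 adjusted over the list alone, adjusted p = 3.19e-05), with KDM3A higher by 0.99 ± 0.056 and KDM5B by 0.39 ± 0.052. KDM3A is also in the HIF target list. KDM2B (0.289) rose as well, but its other probes differed by 0.053 and −0.005.

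**Figure D1:**
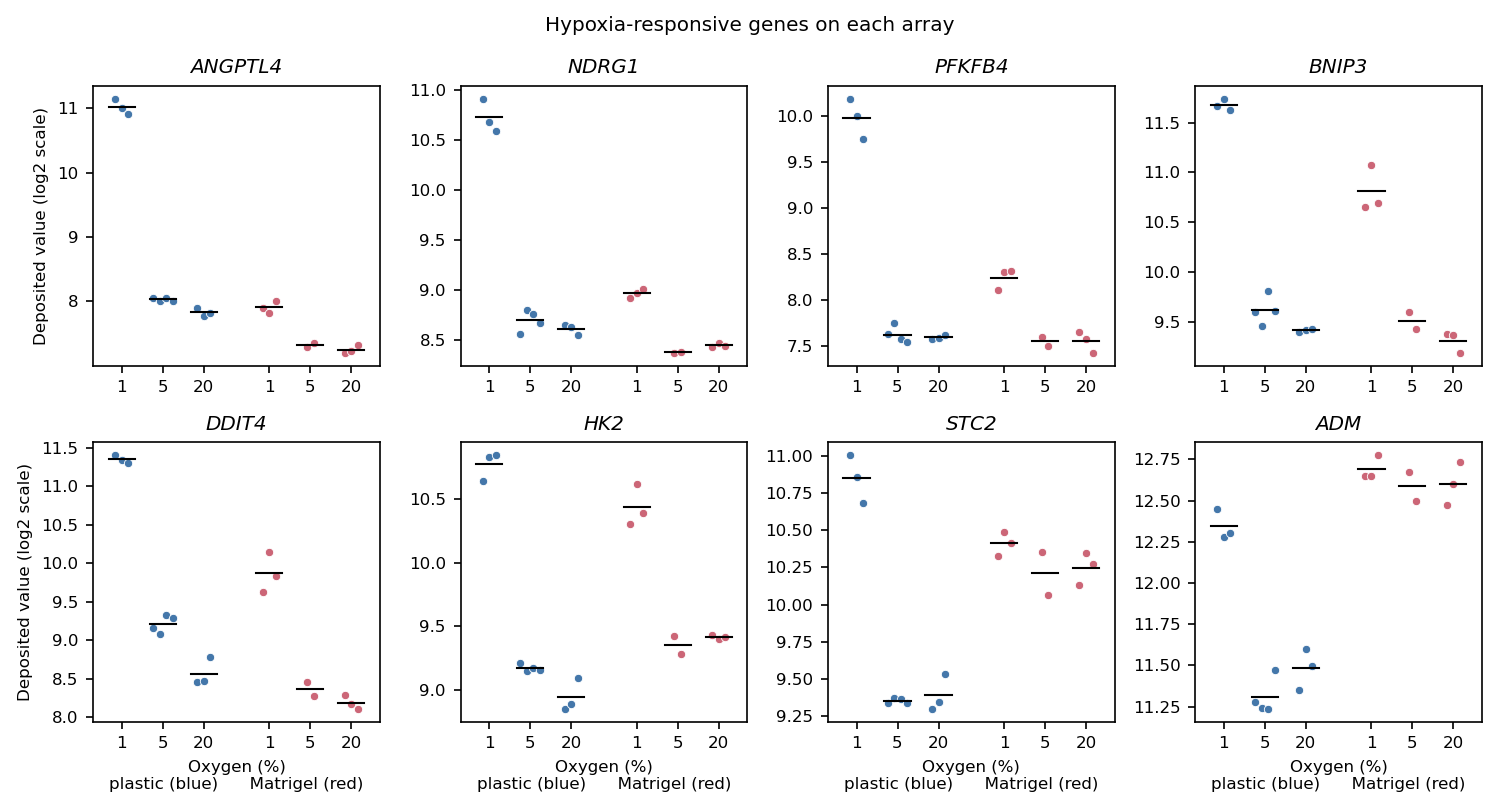
Deposited value (log2 scale, y axis) of 8 hypoxia-responsive genes on each of the 18 arrays, by oxygen percentage (x axis) and substrate. Points are arrays and bars are group means; ANGPTL4 reached 11.02 at 1% oxygen on plastic and 7.91 on Matrigel, while ADM lay near 12.6 at every oxygen level on Matrigel.

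Immediate early and inflammatory cytokine genes were lower as lists at 1% oxygen on plastic. Of 21 immediate early genes 5 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 3.03e-06). EGR1, a transcription factor induced within minutes by mitogens, fell by 0.70 ± 0.078 and DUSP5, a phosphatase acting on ERK, by 0.40 ± 0.065, whereas JUN rose by 0.29 ± 0.053. Of 17 inflammatory cytokine genes 5 fell and none rose (7 adjusted over the list alone, adjusted p = 0.00231), among them IL11 by 0.62 ± 0.074, CXCL8, which encodes interleukin 8, by 0.57 ± 0.10 and CCL2 by 0.25 ± 0.051. In the list of 20 angiogenic factors, 6 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 0.0144). The mean of that list was 0.216 and its median −0.0039, since ANGPTL4, ADM, ANG and EFNA1 rose while CXCL8 fell. MMP1, an interstitial collagenase, fell by 0.59 ± 0.075, and PLAUR, the urokinase receptor, did not pass (−0.12 ± 0.044, adjusted p = 0.142). HLA-G, a marker of extravillous trophoblast, differed by 0.20 ± 0.063 (adjusted p = 0.0828), and passed at an adjusted p of 0.0135 without replicate 1 of the 1% arrays. All 6 lists kept their calls with an estimated correlation. Without replicate 1 or replicate 3 of the 1% arrays on plastic, the count fell to 301 or 325.

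On Matrigel the same question found a narrower set of genes, with the hypoxia response again on top. DDIT4 rose 2.83-fold between 5% and 1% oxygen, from 8.37 ± 0.13 (SD, n = 2) to 9.87 ± 0.26 (SD, n = 3). BNIP3 rose 2.46-fold, HK2 2.12-fold, BHLHE40, a transcriptional repressor of the circadian clock, 1.97-fold, AK4, a mitochondrial adenylate kinase, 1.80-fold and SLC2A3 1.70-fold, with adjusted p from 2.9e-07 to 1.1e-05. Dimmer probes above the filter gave smaller log2 differences, 0.54 against 1.09 for HK2 and 0.39, 0.28 and 0.42 against 0.85 for AK4. ANGPTL4 and NDRG1 rose less, by 0.58 ± 0.066 and 0.59 ± 0.078 on the log2 scale, and the dimmer ANGPTL4 probes differed by 0.020 ± 0.038 and 0.14 ± 0.097. Of 37 HIF targets 11 rose and none fell (17 adjusted over the list alone, adjusted p = 1.7e-37), and of 22 glycolysis genes 7 rose (10 adjusted over the list alone, adjusted p = 2.18e-24). ADM, at 12.59 at 5% and 12.69 at 1% oxygen, did not pass (0.10 ± 0.089, adjusted p = 0.993), nor did VEGFA (0.24 ± 0.057, adjusted p = 0.149), LOX, HIF1A, EPAS1, PDK1, EGLN3, PLAUR or HLA-G.

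In total 26 genes passed on Matrigel, 24 higher and 2 lower at 1% oxygen, and 764 had an unadjusted p under 0.05. With no difference in any gene, a share of 0.05 of the 12886 tested would do so, so much of the 764 is expected by chance. Metallothioneins were called higher as a list, and mitosis, heat shock and endoplasmic reticulum (ER) stress genes lower. With an estimated correlation those calls were lost, at adjusted p of 0.13, 0.321, 0.0578 and 0.0578, and none of their 5, 25, 13 and 21 members passed singly. Adjusted over the list alone, 1 metallothionein rose, 3 ER stress genes fell and 1 rose, and no member passed in the others. The group at 5% oxygen holds 2 arrays. The count fell to 16 without its replicate 2, to 15 without its replicate 3 and to 17 without replicate 3 at 1% oxygen, and 15 genes passed when only the arrays compared were fitted.

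The oxygen differences on both substrates rest on separate arrays and were compared directly. Their calls share each gene's estimate of the spread, so a gene with a small spread passes more easily in both. Genes are not independent either, so the counts for independent lists and the hypergeometric p are only a rough guide. Of the 24 genes higher at 1% oxygen on Matrigel, 22 were also among the 319 higher on plastic, against 0.594 for independent lists (exact one-sided hypergeometric p = 5.87e-34). The 2 lower genes on Matrigel were too few for such a comparison (0 shared with the 207 lower on plastic, against 0.0321), and at an unadjusted p under 0.01 the lower genes shared 13, against 3.32 for independent lists (exact one-sided hypergeometric p = 2.64e-05). Across all genes, which are not independent replicates, the log2 differences correlated at r = 0.307 (Spearman's rho 0.11). The rise was smaller on Matrigel. The interaction passed for 75 genes, 60 of them with a smaller or more negative difference on Matrigel, and for 17 of 37 HIF targets (27 adjusted over the list alone, camera adjusted p = 3.08e-50, or 3.45e-05 with an estimated correlation). Those with the smallest p were ANGPTL4, whose interaction was −2.41 ± 0.086 on the log2 scale, PFKFB4 with −1.67 ± 0.13, NDRG1 with −1.44 ± 0.10, STC2 with −1.29 ± 0.12 and ANKRD37 with −0.83 ± 0.073. For DDIT4, BHLHE40 and SLC2A1 the interaction did not pass, at adjusted p of 0.0758, 0.441 and 0.458. That of DDIT4 passed under 3 alternatives, at 0.00749 without replicate 2 at 1% oxygen on Matrigel, and that of SLC2A1 at 0.0392 without replicate 4 at 1% oxygen on plastic. In the opposite direction, 3 of 21 immediate early genes (7 adjusted over the list alone) had a higher difference on Matrigel (adjusted p = 5.01e-08, or 0.000492 with an estimated correlation), led by EGR1 with 0.86 ± 0.12. Without replicate 2 or 3 at 5% or replicate 1 at 1% oxygen on Matrigel, or replicate 3 at 5% on plastic, 40, 39, 47 or 49 interactions passed.

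**Figure D2:**
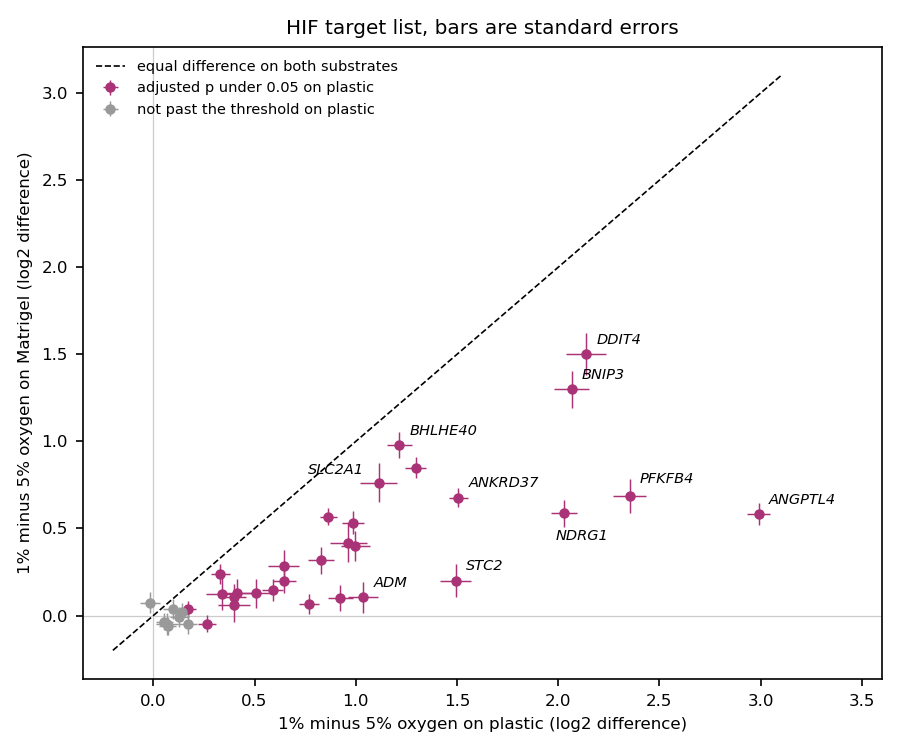
Difference between 1% and 5% oxygen of the 37 HIF targets on plastic (x axis) and on Matrigel (y axis), both as log2 differences, with standard errors as bars. The dashed line marks equal differences; ANGPTL4 lies at 2.99 and 0.58, STC2 at 1.49 and 0.20, and BHLHE40 at 1.22 and 0.98.

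The comparison of 1% with 20% oxygen on plastic shares its 1% arrays with the comparison against 5%, so both sets of differences are not independent. ANGPTL4 was 9.14-fold higher, DDIT4 6.88-fold, PFKFB4 5.21-fold, BNIP3 4.82-fold, NDRG1 4.33-fold, HK2 3.54-fold and ANKRD37 3.52-fold. Dimmer probes gave smaller log2 differences, 0.419 and 0.835 against 3.192 for ANGPTL4 and 0.957 against 1.825 for HK2. Of 37 HIF targets 30 rose (32 adjusted over the list alone, adjusted p = 4.58e-81) and of 22 glycolysis genes 17 rose (19 adjusted over the list alone, adjusted p = 1.99e-34), with no member lower in either. SLC2A1 rose by 1.29 ± 0.099, ADM by 0.86 ± 0.080, VEGFA by 0.42 ± 0.051 and LOX by 0.31 ± 0.046. Angiogenic factors had 6 higher and 1 lower of 20 (6 and 3 adjusted over the list alone, adjusted p = 0.00605), inflammatory cytokines 2 lower of 17 (5 adjusted over the list alone, adjusted p = 0.00605) and JmjC demethylases 2 higher of 15 (4 adjusted over the list alone, adjusted p = 0.000107). Among the larger decreases were CXCL8 by 0.58 ± 0.11, EGR1 by 0.57 ± 0.084, IL11 by 0.52 ± 0.080 and CCN1, a matricellular protein gene, by 0.48 ± 0.073. The immediate early list, called lower against 5% oxygen, was not called against 20% (adjusted p = 0.138). HIF1A, EPAS1, PDK1, EGLN3, PLAUR and HLA-G did not pass. In all 535 genes passed, 351 higher and 184 lower, and all 5 lists held with an estimated correlation.

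On Matrigel, 1% against 20% oxygen raised DDIT4 (3.21-fold), BNIP3 (2.83-fold), HK2 (2.03-fold), AK4 (1.95-fold), ANKRD37 (1.91-fold) and SLC2A3 (1.91-fold). Dimmer probes above the filter gave smaller log2 differences, 0.34 against 1.02 for HK2 and 0.43, 0.34 and 0.27 against 0.96 for AK4. Of 37 HIF targets 14 rose (20 adjusted over the list alone, adjusted p = 1.07e-30) and of 22 glycolysis genes 8 rose (15 adjusted over the list alone, adjusted p = 2.1e-21). Decreases included ASNS, asparagine synthetase, by 0.82 ± 0.078 from 10.11 ± 0.13 (SD, n = 3), PSAT1, of serine synthesis, by 0.69 ± 0.065, and TRIB3, a pseudokinase induced by ATF4, by 0.59 ± 0.056. These were the 3 of 21 ER and integrated stress response genes that fell (4 fell and 1 rose adjusted over the list alone, adjusted p = 0.00716), and each of their interactions with substrate passed, at −0.98 ± 0.11, −0.58 ± 0.091 and −0.55 ± 0.080. Immediate early genes had 3 higher of 21 (6 higher and 1 lower adjusted over the list alone, adjusted p = 5.81e-05), among them JUN by 0.54 ± 0.057 and PHLDA1 by 0.38 ± 0.070. Heat shock genes had 4 higher of 13 (7 adjusted over the list alone, adjusted p = 5.81e-05), led by HSPA1B with 0.43 ± 0.063 and DNAJB1 with 0.34 ± 0.056.

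The matrix and integrin list was called higher at 1% than at 20% oxygen on Matrigel with 1 of 33 members passing, also 1 adjusted over the list alone (adjusted p = 0.00143), and lost the call at an adjusted p of 0.186 with an estimated correlation. The other 5 lists kept theirs. In total 190 genes passed, 132 higher and 58 lower. VEGFA, ADM, LOX, HIF1A, PDK1, EGLN3, PLAUR and HLA-G did not pass, and EPAS1 (−0.25 ± 0.062) missed the threshold at an adjusted p of 0.0504, which 5 alternatives took below it, to 0.0278 with array weights. The count was 331 with array weights, and 95, 93 or 118 without replicate 2 at 1%, replicate 1 at 20% or replicate 2 at 20% oxygen. The interaction of substrate with 1% versus 20% oxygen passed for 118 genes, 79 of them lower on Matrigel, and for 19 of 37 HIF targets (27 adjusted over the list alone, camera adjusted p = 1.3e-47), with ANGPTL4 (−2.53 ± 0.083), PFKFB4 (−1.69 ± 0.12), NDRG1 (−1.60 ± 0.098), STC2 (−1.29 ± 0.12) and ANKRD37 (−0.88 ± 0.070) at the smallest p.

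The 5% cultures were set against 20% to see what the choice of normoxia changes. On plastic 3 genes passed, all higher at 5% oxygen: DDIT4 by 0.64 ± 0.099, ANKRD37 by 0.31 ± 0.047 and PLAUR by 0.26 ± 0.044, with adjusted p of 0.0207, 0.0207 and 0.038. ANGPTL4 (0.20 ± 0.055), SLC2A1 (0.17 ± 0.093), VEGFA (0.091 ± 0.048) and NDRG1 (0.088 ± 0.065) did not pass, nor did HIF1A, EPAS1, ADM, PDK1, EGLN3, LOX and HLA-G. An unadjusted p under 0.05 was reached by 727 genes. Much of that number is expected by chance, as a share of 0.05 of the 12886 tested would reach it with no difference. None of the 3 calls remained when only the arrays compared were fitted, or without replicate 1, 3 or 4 at 5% or replicate 2 or 3 at 20% oxygen. PLAUR had 2 further probes, which differed by 0.20 ± 0.053 and 0.077 ± 0.069.

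Immediate early genes were higher as a list at 5% than at 20% oxygen on plastic, with the 5% arrays that also enter its lower call at 1% oxygen, although none of 21 passed singly (3 rose adjusted over the list alone, adjusted p = 1.06e-05). JUNB (0.14 ± 0.040) and PHLDA1 (0.21 ± 0.065) had the smallest p among them, and the call held with an estimated correlation at an adjusted p of 0.00351. A further 5 lists were called only with the preset correlation. With an estimated correlation the adjusted p were 0.127 for HIF targets (2 of 37 rose), 0.194 for glycolysis (0 of 22), 0.0578 for invasion proteases (1 of 22), 0.0592 for cholesterol synthesis, which was lower (0 of 18), and 0.0785 for heat shock (0 of 13). Adjusted over the list alone, 6 HIF targets, 2 glycolysis genes, 3 proteases and 2 heat shock genes rose and 3 cholesterol genes fell.

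On Matrigel, chaperone genes were higher at 5% than at 20% oxygen. HSPH1 was higher by 0.58 ± 0.096, HSPA1B, an inducible HSP70, by 0.54 ± 0.071 and DNAJB1, its cochaperone, by 0.52 ± 0.062. HSPA1B stood at 11.96 ± 0.14 (SD, n = 2) at 5% and 11.42 ± 0.048 (SD, n = 3) at 20% oxygen. In the heat shock list 5 of 13 members rose and none fell (7 adjusted over the list alone, adjusted p = 1.14e-07, or 0.00126 with an estimated correlation). The mean of this list, centred per gene, was −0.177 to −0.145 on the 20% arrays on Matrigel and at least −0.017 on every other array. SRSF5, a splicing factor, was lower at 5% oxygen by 0.60 ± 0.092, ASNS by 0.48 ± 0.087, CITED4 by 0.45 ± 0.066 and CIRBP, a cold-inducible RNA-binding protein, by 0.44 ± 0.081. Of the oxygen-related genes fixed beforehand, HIF1A, EPAS1, VEGFA, SLC2A1, PDK1, EGLN3, ANGPTL4, ADM, NDRG1, PLAUR, LOX and HLA-G, none passed.

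In this comparison 126 genes passed, 87 higher and 39 lower at 5% oxygen. Respiratory chain genes were called lower, and matrix, mitosis and immediate early genes higher. None of their 32, 33, 25 and 21 members passed singly, and with an estimated correlation the adjusted p were 0.348, 0.279, 0.279 and 0.145. Adjusted over the list alone, 4 immediate early genes rose and 1 fell, and no member of the other 3 passed. The count is unstable. It was 18 and 44 without replicates 2 and 3 at 5% oxygen, 35 and 82 without replicates 1 and 2 at 20%, and 270 with array weights. Without replicate 2 at 5% oxygen, HSPH1 (adjusted p = 0.133) and SRSF5 (0.0582) no longer passed, nor did CIRBP (0.133 and 0.0799) and ASNS (0.13 and 0.0799) without replicate 2 or replicate 3. The interaction of substrate with 5% versus 20% oxygen passed for SIN3B, a corepressor subunit, with 0.51 ± 0.065 (adjusted p = 0.00316), with 1 to 3 genes called when single arrays were left out, and the heat shock list was called in it too (0 of 13 members, 4 adjusted over the list alone, adjusted p = 0.00017, or 0.0126 with an estimated correlation).

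**Figure D3:**
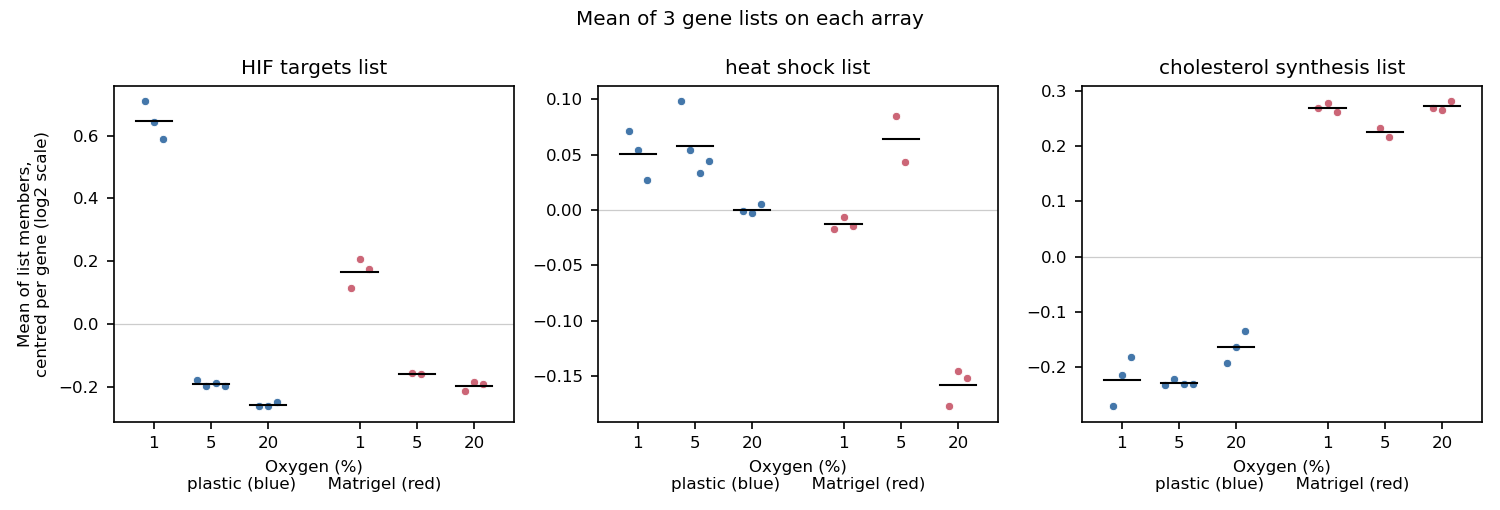
Mean over the members of 3 gene lists on each array, after subtracting each gene's mean over the 18 arrays (log2 scale, y axis), by oxygen percentage (x axis) and substrate. Points are arrays and bars group means; HIF targets reached 0.589 to 0.709 at 1% oxygen on plastic and 0.115 to 0.206 on Matrigel, and all 8 Matrigel arrays lay above all 10 plastic arrays for cholesterol synthesis.

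Substrate changed more genes than oxygen. Within 1%, 5% and 20% oxygen alone, 2907, 2604 and 3014 genes passed between Matrigel and plastic. Averaged over the oxygen levels, 5281 of 12886 genes passed between Matrigel and plastic, 2380 higher and 2901 lower on Matrigel, most by little: 99 rose and 69 fell by at least 1.5-fold. LBH, a transcriptional coregulator, was 3.29-fold higher on Matrigel (its dimmer probe above the filter by 0.55 ± 0.034 on the log2 scale), EDN1, which encodes the vasoconstrictor endothelin 1, 2.94-fold, ARID5B 2.77-fold, ACTA2, smooth muscle actin, 2.67-fold, MGP, an inhibitor of matrix calcification, 2.65-fold and IGFBP5 2.46-fold. ANGPTL4 was 2.76-fold lower on average, with differences of −3.11, −0.70 and −0.58 at 1%, 5% and 20% oxygen, OAF 2.37-fold, G0S2 2.02-fold, CGA, the common α subunit of the glycoprotein hormones, 1.99-fold and PHLDA1 1.97-fold. At 20% oxygen alone CGA stood at 8.53 ± 0.088 (SD, n = 3) on plastic and 7.52 ± 0.020 (SD, n = 3) on Matrigel. When arrays were centred on the median of the tested genes, 50.6% rather than 45.1% of the calls were higher on Matrigel.

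Cholesterol synthesis was the list set apart most clearly. Of 18 measured members 15 rose and 1 fell on Matrigel, the same numbers adjusted over the list alone (adjusted p = 1.22e-11, or 0.000394 with an estimated correlation). HMGCS1, of the mevalonate pathway, was higher by 1.17 ± 0.035, DHCR7 by 0.95 ± 0.042 and MVD by 0.77 ± 0.036. Mitosis genes fell, 19 of 25 with none higher (19 adjusted over the list alone, adjusted p = 1.45e-05), including CENPF by 0.57 ± 0.052 and AURKB by 0.35 ± 0.034. Of 22 invasion proteases and their regulators 10 fell and 2 rose (10 and 2 adjusted over the list alone, adjusted p = 0.00971), with PLAU, urokinase, lower by 0.75 ± 0.033, MMP9 by 0.74 ± 0.035, MMP1 by 0.80 ± 0.047 and PLAUR by 0.29 ± 0.027. Matrix and integrin genes had 21 higher and 7 lower of 33 (the same adjusted over the list alone, adjusted p = 1.54e-05), with CCN1 higher by 1.22 ± 0.043, COL8A1 by 0.90 ± 0.039 and ITGB5 by 0.55 ± 0.027, but this list missed the threshold with an estimated correlation (adjusted p = 0.0572).

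TGF-β targets had 9 higher and 2 lower of 19 (9 and 3 adjusted over the list alone), with TGFB2 higher by 1.23 ± 0.058 and CCN2 by 0.80 ± 0.038. NRF2 targets had 7 higher and 1 lower of 14 (8 and 1 adjusted over the list alone), with TXNRD1, thioredoxin reductase, higher by 0.84 ± 0.053. ER and integrated stress response genes had 10 higher and 3 lower of 21, the same adjusted over the list alone, with TRIB3 higher by 0.64 ± 0.033 and ATF3, a stress-induced transcription factor, by 0.38 ± 0.023. These lists share an adjusted p of 0.00971. Mesenchymal and stromal genes had 9 higher and 5 lower of 19, the same adjusted over the list alone, with CDH11 higher by 0.55 ± 0.037, at an adjusted p of 0.0207 that became 0.08 with an estimated correlation. Angiogenic factors had 10 higher and 5 lower of 20 (the same adjusted over the list alone, adjusted p = 0.0207).

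Of 12 genes of the HIF pathway 6 were higher and 1 lower on Matrigel, the same adjusted over the list alone (adjusted p = 0.0132). CITED2, a coregulator that restrains HIF, was higher by 1.14 ± 0.028, EGLN3 by 0.28 ± 0.034, HIF1A by 0.28 ± 0.041 and EPAS1 by 0.098 ± 0.036, the last with an adjusted p of 0.039 that 11 of the 18 fits without 1 array raised above the threshold, up to 0.0877 without replicate 2 at 5% oxygen on Matrigel. HIF targets had 19 lower and 5 higher of 37, the same adjusted over the list alone (adjusted p = 0.0121, or 0.265 with an estimated correlation). This average includes the 1% arrays. At 5% oxygen the median difference of the 29 members that rose on plastic was −0.0039 (95% bootstrap interval over genes −0.0702 to 0.0539). NDRG1 was lower by 0.75 ± 0.041 on average, with differences of −1.76, −0.32 and −0.17 at 1%, 5% and 20% oxygen, and ADM higher by 0.91 ± 0.047, with ADM at 12.60 ± 0.13 on Matrigel and 11.48 ± 0.12 on plastic in 20% oxygen (SD, n = 3 each). VEGFA, SLC2A1, PDK1 and LOX did not pass, and HLA-G was higher by 0.25 ± 0.040. Of the 11 lists called between Matrigel and plastic, 8 held with an estimated correlation, at adjusted p of at most 0.0466.

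Of 14 endothelial marker genes 6 lay above the filter and 1 above a value of 8 (SOX18, 9.41), and of 13 leukocyte genes with a named probe 5 and 2 did so, CD68 (9.25) among them. CD14 and CD68 were lower on Matrigel, by 0.55 ± 0.038 and 0.39 ± 0.057, and TIE1 was lower and TEK higher, by 0.26 ± 0.031 and 0.17 ± 0.025. Camera called neither list in any of the 7 group comparisons. Fry, which tests a list without comparing it with other genes, called the leukocyte list lower on Matrigel (adjusted p = 1.62e-06), higher at 1% than at 20% oxygen on plastic (0.00394) and lower at 5% than at 20% on Matrigel (0.0401).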

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

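The tests behind both patterns weighed here, HIF targets rising less on Matrigel and chaperone genes at 5% oxygen on Matrigel, were chosen after the results had been seen; RBM3 was named after its values were seen.

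HIF targets rose less between 5% and 1% oxygen on Matrigel than on plastic. The median ratio of the rises was 0.314 (95% bootstrap interval 0.252 to 0.442, 10000 draws) over the 29 members that passed on plastic. That choice of members lowers the ratio. Over all 37 measured, the ratio of the mean rises was 0.386 (0.292 to 0.479). These intervals, and those below, resample genes, which are not independent, and leave out the spread between arrays. The group at 5% oxygen on Matrigel holds 2 arrays. Compression at the bottom of the scale predicts ratios near 1 for bright genes, and for dimmer genes whose levels at 5% oxygen differed by at most 0.2 between substrates, but the median ratio was 0.434 (0.145 to 0.656) for 13 such members with levels above 9 and 0.306 (0.252 to 0.399) for 13 such lower members, and without the choice the ratios of means were 0.459 (0.303 to 0.593) for 15 and 0.313 (0.22 to 0.391) for 18. A single atypical array is argued against by the mean rise per array, at most 0.364 on Matrigel and at least 0.779 on plastic. A common factor on every response, on the deposited scale, is argued against too. On that scale 10 of the 29 members lay more than 3 SE from the common ratio of 0.37. BHLHE40 (0.805) and DDIT4 (0.702) lay above it, and STC2 (0.134) and INSIG2 (0.107) below it. BHLHE40 and STC2 had levels above 9 at 5% oxygen on both substrates. A common factor combined with compression of dim members, such as INSIG2, was not tested. At 5% oxygen 4 of the 29 passed as higher on Matrigel, while the median difference was −0.0039. ADM (1.278), STC2 (0.857) and PLOD2 (0.468) started higher there, with ratios of 0.102, 0.134 and 0.0846. Members that started lower went both ways. DDIT4 (−0.844, ratio 0.702), BHLHE40 (−0.649, 0.805) and PFKFB3 (−0.324, 0.656) had ratios above the common one. ANGPTL4 (−0.704, 0.195) and NDRG1 (−0.321, 0.29) had ratios below it. INSIG2 (0.067, ratio 0.107) started nearly level. Whether the starting level limits the rise was not tested. Also open is a different oxygen exposure of the cells that acts unequally on genes, which was not measured. So is an effect of the substrate on how cells respond, which may be biological and is a hypothesis only.

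Chaperone genes of the heat shock list were higher at 5% than at 20% oxygen on Matrigel, by 0.222 on average over 13 members. The main axis of variation between replicates, taken from the other 4 groups, did not account for this. The mean was 0.217 after its removal (camera adjusted p = 2.22e-07). That axis held 18.8% of the spread within those groups, and its correlation across genes with the difference was 0.2 in size. Its removal was therefore a weak test. It cannot speak to variation particular to the 5% and 20% arrays on Matrigel. A sealed-chamber effect of equal size on both substrates predicts no difference between substrates. For 5% versus 20% oxygen that difference was 0.164 on average (camera adjusted p = 0.00017). The list was, however, singled out for its difference on Matrigel in these same arrays. For 1% versus 20% oxygen, again chamber against open plates, it was 0.0947 (camera adjusted p = 0.0496, or 0.0775 with an estimated correlation). An equal chamber effect is therefore not settled. A temperature difference between chamber and open plates on Matrigel alone cannot be told apart from oxygen, because every 5% array came from the chamber and every 20% array did not. RBM3, an RNA-binding protein induced by cold, was lower at 5% oxygen by −0.366 ± 0.075 on Matrigel (adjusted p = 0.0195) and did not pass on plastic (−0.082 ± 0.062), but it was also lower at 1% than at 20% oxygen on plastic (−0.327 ± 0.067, adjusted p = 0.00583) and on Matrigel (−0.281 ± 0.067, adjusted p = 0.0402), while CIRBP, likewise induced by cold, was lower at 5% oxygen on Matrigel (−0.438 ± 0.081) and did not pass on plastic at 5% (−0.038 ± 0.067) or 1% (0.022 ± 0.072), nor at 1% on Matrigel (−0.222 ± 0.072, adjusted p = 0.141), with interactions for 5% versus 20% that did not pass for either gene (adjusted p = 0.415 and 0.259).

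Splits of the arrays into other groups of the same sizes were counted for oxygen comparisons with at least 3 arrays per group. For Matrigel versus plastic, which includes the group of 2 arrays, substrate labels were permuted within each oxygen level. For the interaction of 1% versus 20% oxygen they were permuted within these levels after removing the mean substrate effect. For 1% versus 5% oxygen on plastic, 1 of 35 splits, the real one, gave as many as 526 genes, and the highest other gave 113. For Matrigel versus plastic 1 of 100 splits, the real one beside others drawn at random, reached 5281, and the highest other gave 129. For the interaction of substrate with 1% versus 20% oxygen 1 of 100, likewise the real one, reached 118, and the highest other gave 15. A share under 0.05 in these comparisons argues against a chance split of these arrays. It cannot speak to chance differences between cultures, since the replicates may be technical. For 5% versus 20% oxygen on plastic 3 of 35 splits gave at least the 3 genes called, so chance is not excluded. The highest other split gave 27, several times the real count, which may reflect a structure of these arrays and was not tested further. For 1% versus 20% oxygen 10 splits are too few for a share under 0.05; the real splits, 1 of 10 each, gave 535 genes on plastic, with 2 in the highest other, and 190 on Matrigel, with 0.

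Single arrays stood apart from the others of their group for 4 of 149 genes examined in the 4 arrays at 5% oxygen on plastic, against 7.45 expected by chance. AGO2 read 10.813 in 1 array and 10.474 on average in the others, DHCR7 9.895 and 9.76, FSTL3 8.392 and 8.256, and GBP1 8.306 and 8.221.

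The interaction of 1% versus 5% oxygen passed for 75 genes, and only those taken by the naming rule are given here. Others, such as PLOD2 and INSIG2 (adjusted p = 3.28e-05 and 0.00011), passed too. The difference between 1% and 5% oxygen was lower on Matrigel than on plastic, by the test of the interaction, for ADM (−0.93), AK4 (−0.45), ANG (−0.39), ANGPTL4 (−2.41), ANKRD37 (−0.83), BNIP3 (−0.77), HK2 (−0.51), KDM3A (−0.45), LOX (−0.31), NDRG1 (−1.44), PFKFB3 (−0.3), PFKFB4 (−1.67), STC2 (−1.29) and THBS2 (−0.46). It was higher for CCL2 (0.45), CXCL8 (0.84), DUSP5 (0.47), EGR1 (0.86), IL11 (0.53), MMP1 (0.54), PLAUR (0.34) and SPRY4 (0.46). PLAUR passed on neither substrate alone, and its value rests on its brightest probe. Its dimmer probes differed by 0.034 and −0.161 on plastic and by 0.027 and −0.013 on Matrigel. As lists, HIF targets (mean −0.514), glycolysis (−0.269), angiogenic factors (−0.194), ER stress genes (−0.0899) and JmjC demethylases (−0.137) were lower, and inflammatory cytokines (0.192) and immediate early genes (0.193) higher. Mitosis genes were lower too (−0.0814), at an adjusted p of 0.272 with an estimated correlation.

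Of the 118 genes whose interaction passed for 1% versus 20% oxygen, likewise only those taken by the naming rule are given. The difference between 1% and 20% oxygen was lower on Matrigel for ADM (−0.77), AK4 (−0.4), ANG (−0.49), ANGPTL4 (−2.53), ANKRD37 (−0.88), ASNS (−0.98), BHLHE40 (−0.59), BNIP3 (−0.77), DDIT4 (−1.1), HK2 (−0.8), KDM3A (−0.66), NDRG1 (−1.6), PFKFB3 (−0.45), PFKFB4 (−1.69), PSAT1 (−0.58), SLC2A3 (−0.43), STC2 (−1.29) and TRIB3 (−0.55). It was higher for BCL2L1 (0.48), CCN1 (0.62), CXCL8 (1.22), DNAJB1 (0.35), EGR1 (0.63), IL11 (0.65) and PHLDA1 (0.44). As lists, HIF targets (mean −0.543), glycolysis (−0.295), ER stress genes (−0.155) and JmjC demethylases (−0.113) were lower and immediate early genes (0.194) higher. Angiogenic factors (−0.134), leukocyte markers (−0.142), inflammatory cytokines (0.161), interferon genes (−0.0786) and heat shock genes (0.0947) had adjusted p of 0.0664, 0.0602, 0.0602, 0.0602 and 0.0775 with an estimated correlation. For 5% versus 20% oxygen the interaction passed for SIN3B (0.51), and as lists for heat shock genes (0.164) and leukocyte markers (−0.139), the latter at 0.149 with an estimated correlation.

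Probes without a gene name carried signal as well: 53 of 6289 passed between 1% and 5% oxygen on plastic, 41 of them higher at 1%, and 2 on Matrigel, both higher. Between 1% and 20% oxygen 55 passed on plastic, 42 of them higher, and 35 on Matrigel, 14 of them higher. Between 5% and 20% oxygen 0 passed on plastic and 10 on Matrigel, 3 of them higher, and between Matrigel and plastic 1318 passed, 706 of them higher on Matrigel.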

How the results depend on the processing

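The tests of unnamed probes and of each gene's other probes were chosen after seeing the data; all other alternatives reported in this part were fixed beforehand. No result that passed as reported or under an alternative changed sign under the latter. Sign changes of results that passed in neither were not counted. Single other probes of some genes had the opposite sign, among them FANCB (0.147 ± 0.065 against −0.408, 1% versus 20% oxygen on Matrigel) and TFAP2A (−0.091 ± 0.023 against 0.321, Matrigel versus plastic). Of 319 results for named genes, called or not (245 passed as reported), 259 kept their side of the threshold under every alternative run. Over all alternatives of these results, 6519 values stayed on the same side of the threshold, 226 lost it and 17 gained it. A second quantile normalization moved values by at most 8.6e-05 and so tested nothing. Dim probes lie close to the lower end of the scale, which limits what their differences show. The cause of the changes below was not tested, except that stricter thresholds and fewer arrays call fewer genes by construction.

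With a 1.5-fold minimum, 48, 11, 48, 18, 1, 3 and 168 genes passed for 1% versus 5% oxygen on plastic and on Matrigel, 1% versus 20% on plastic and on Matrigel, 5% versus 20% on plastic and on Matrigel, and Matrigel versus plastic, and 21, 32 and 0 for the interactions of 1% versus 5%, 1% versus 20% and 5% versus 20%. At an adjusted p under 0.01 there were 251 (1% versus 5% on plastic), 280 (1% versus 20% on plastic), 86 (1% versus 20% on Matrigel), 0 (5% versus 20% on plastic), 25 (5% versus 20% on Matrigel), 33 (interaction, 1% versus 5%) and 66 (interaction, 1% versus 20%). Array weights gave 331 genes for 1% versus 20% and 270 for 5% versus 20% oxygen on Matrigel. With only the arrays compared, 15 passed for 1% versus 5% on Matrigel and 0 for 5% versus 20% on plastic, where limma gave 727 unadjusted p under 0.05 in the fit to all arrays. The interaction of 5% versus 20% gave 2 genes with centred arrays, the mean of probes, an intensity trend or array weights, and 50% rather than 100% of its calls were positive after centring.

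Without 1 array, counts ran from 301 to 500 for 1% versus 5% oxygen on plastic, 15 to 22 on Matrigel, 93 to 175 for 1% versus 20% on Matrigel, 0 to 3 and 18 to 84 for 5% versus 20% on plastic and Matrigel, and 39 to 86 and 1 to 3 for the interactions of 1% versus 5% and 5% versus 20%. In this order the lowest came without replicate 1 at 1% on plastic, replicate 3 at 5% on Matrigel, replicate 1 at 20% on Matrigel, several arrays (5% versus 20% on plastic), replicate 2 at 5% on Matrigel, replicate 3 at 5% on Matrigel, and several arrays again. Where this left 1 array at 5% oxygen on Matrigel, it is assumed to vary like the others. Of the gene lists, fry called 11 and 15 for 1% versus 5% and 1% versus 20% on plastic, 10 for 1% versus 20% on Matrigel and 22 for Matrigel versus plastic. Camera with an estimated correlation called 2 for 1% versus 5% on Matrigel and 1 each for 5% versus 20% on plastic and on Matrigel. At an unadjusted p under 0.01, 60 higher and 13 lower genes were shared by both substrates for 1% versus 5% oxygen.

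Replicate numbers did not pair the arrays. Deviations of 34 same-numbered pairs correlated at a median of −0.022 (−0.24 to 0.24), with 4 above 0.1, against 0.0089 for 100 other pairs, and 4 of 18 arrays correlated best with their own number. With the replicate number as a block, camera also called extravillous trophoblast markers for Matrigel versus plastic (adjusted p = 0.0403) and apoptosis genes for 1% versus 5% oxygen on Matrigel (0.0405). It lost its call of mitosis genes in the latter comparison (0.0969). In the main fit 1 of 18 apoptosis genes passed in that comparison, BNIP3, which is also a HIF target. The median difference of the apoptosis list was −0.0104 and its mean 0.108. With this block 0 rather than 3 genes passed for 5% versus 20% oxygen on plastic, and the other counts stayed within 1.5 times.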

Other observations

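All comparisons here were planned, apart from the look at the other probes of TFAP2A, which was chosen after seeing the data, and no further hypothesis was tested. Between Matrigel and plastic, single members of lists that were not called as lists moved in both directions. Among inflammatory cytokines, 7 of 17 were higher and 4 lower on Matrigel, with CCL2 higher by 0.58 ± 0.032 and CXCL8 lower (−0.76 ± 0.063; camera adjusted p = 0.441). Interferon response genes had 3 higher and 4 lower of 19 (adjusted p = 0.793), with GBP1, an interferon-induced GTPase, at 0.58 ± 0.028 and ISG20, an exonuclease, at −0.46 ± 0.038. Of 11 Notch pathway genes 6 were higher and 2 lower (adjusted p = 0.265), NOTCH1 at 0.28 ± 0.041 and its target HES1 at −0.35 ± 0.046. Immediate early genes had 7 higher and 9 lower of 21 (adjusted p = 0.737), among them DUSP5 at 0.48 ± 0.041 and PHLDA1 at −0.98 ± 0.041. Apoptosis genes had 4 higher and 3 lower of 18 (adjusted p = 0.385), with PMAIP1, a BH3-only activator of cell death, at 0.68 ± 0.040. DNA replication genes had 9 higher and 2 lower of 25 (adjusted p = 0.171), with UHRF1 at 0.33 ± 0.046 and RRM1 at −0.31 ± 0.029. Glycolysis had 1 higher and 8 lower of 22 (adjusted p = 0.134), with GPI at −0.51 ± 0.052, and the respiratory chain 1 higher and 11 lower of 32 (adjusted p = 0.147), with NDUFB5 at −0.26 ± 0.036.

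Lineage markers also went both ways between Matrigel and plastic. Extravillous trophoblast markers had 5 higher and 1 lower of 11 (adjusted p = 0.0708), with FSTL3 at 0.46 ± 0.028 and ITGA1, an integrin subunit, at 0.45 ± 0.042. Villous trophoblast markers had 5 higher and 3 lower of 13 (adjusted p = 0.793), with CGA at −0.99 ± 0.033 and TFAP2A at 0.32 ± 0.038, with its 4 other probes at 0.38, −0.006, −0.007 and −0.091, and epithelial markers 2 higher of 9 (adjusted p = 0.683), with TJP1 at 0.26 ± 0.035. Endothelial and leukocyte lists, at 1 higher and 1 lower of 6 and 2 lower of 5, had adjusted p of 0.896 and 0.415. JmjC demethylases had 2 higher and 4 lower of 15 (adjusted p = 0.43), with KDM3B at −0.33 ± 0.040, and metallothioneins 1 higher and 2 lower of 5 (adjusted p = 0.508), with MT1X at 0.40 ± 0.038 and MT2A at −0.33 ± 0.035. Heat shock genes had 2 higher and 6 lower of 13 (adjusted p = 0.278), HSPA1B at −0.37 ± 0.037. Ribosomal protein genes had 5 higher and 5 lower of 24 (adjusted p = 0.689) and commonly used control genes 3 higher and 1 lower of 11 (adjusted p = 0.683), with B2M at 0.25 ± 0.042 and SDHA at −0.29 ± 0.040. Of the 29 lists, 11 were called by camera in none of the 7 group comparisons. Fry, which does not compare a list with other genes, called some of these, for Matrigel versus plastic the extravillous (adjusted p = 2.32e-08) and villous trophoblast (0.000445), leukocyte (1.62e-06), apoptosis (0.000246), Notch (0.00469) and DNA replication (0.0115) lists.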
